A study of Mus musculus with 8 samples.

How the data were processed

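Messenger RNA levels were measured in the embryonic mouse cortex on 8 Affymetrix whole-transcript arrays, 2 for each of 4 stages. Per the labels' protocols, cortex was collected from timed pregnant wild-type CD-1 dams with no treatment, total RNA was extracted from frozen tissue with Trizol, and amplified RNA was converted to single-stranded cDNA, fragmented and labelled with biotin. Samples were grouped by the developmental stage in their labels and carry the letter A or B from their titles.

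The deposited values were log2 expression levels per transcript cluster, made by the authors with the RMA method in the Expression Console software over core exons, per the labels. RMA corrects background per array, normalizes between arrays and summarises the probes of a cluster. The log base was not stated and was taken as 2 from the usual output of RMA and from the range of the values, which ran from 1.09 to 14.4. The software version and any filter were not given in the sources used here. Array medians were 7.62 and 7.67 at E11, 7.83 and 7.81 at E13, 7.76 and 7.77 at E15 and 7.64 and 7.61 at E18, so some difference in scale between stages was left, and other scalings were computed as alternatives. Scanner files and scan dates were not used here. For arrays, precision is limited by their number, and a change in the total RNA content of cells is not visible after normalization.

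Rows were named through a table of the platform's annotation. Of 23332 rows, 14996 had exactly 1 gene symbol, 1019 had several and 7317 were unnamed here. The Entrez identifier of 14941 of the rows with 1 symbol was found in a RefSeq gene table, and 0 symbols had to be updated. No gene was named from a row with several symbols. The named rows covered 14860 genes, of which 135 had several rows, and the row with the highest mean over all 8 arrays then stood for the gene.

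Differences between stages were tested on all rows with limma 3.58.1 in R 4.3.3, by lmFit with stage as a factor of 4 levels over all 8 arrays and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All stages shared the estimate of spread per row, with 4 residual degrees of freedom, 1.99 prior degrees of freedom and a median residual SD of 0.123 on the log2 scale. The moderated F-test asked for any difference between stages, and contrasts compared E18 with E11 and each stage with the one before. All adjusted p-values of genes are from limma and two-sided. An exact permutation test of 2 against 2 samples cannot give a p below 0.333 and was not used.

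The test design, the alternatives, the 49 gene lists and the rule for naming genes were fixed before the data were examined, except where the text says that a choice was made later. The lists cover ribosomal proteins and the machinery of translation, cell division, progenitor and neuronal classes, other cell types that a dissected cortex could hold, and metabolic and stress genes. For each list the members past the threshold were counted over all rows and adjusted over the list alone. The median of the list was placed among 10000 random lists matched on mean expression in 20 bins. Lists were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, and by themselves with fry, with Benjamini-Hochberg adjustment over the 49 lists within a comparison. At the preset correlation camera called 28 lists for E18 against E11 (13 higher and 15 lower), 21 for E13 against E11, 23 for E15 against E13 and 20 for E18 against E15. With an estimated correlation it called 0 in each comparison, where the lowest adjusted p was 0.294, 0.482, 0.456 and 0.309, and fry called 38, 25, 28 and 17 lists. For E18 against E11, 6 lists had an unadjusted p under 0.05 with an estimated correlation.

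The genes named were those with exactly 1 symbol and a characterised name that had the 12 largest rises and 12 largest falls from E11 to E18, and the 5 largest each way in each step. They had to pass the threshold with both arrays of a stage on the same side of both arrays of the other. To these were added up to 2 rises and 2 falls past the threshold per list, or the 2 largest differences where none passed, the ribosomal protein genes and their measured paralogs, and all measured subunits of the chromatin remodelling lists. The text names a subset of these. Members of the ribosomal protein list were also tested after the list median of the same array had been subtracted, with adjustment over the list.

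The fit was tested on simulated data for the comparison of E18 with E11, with 23332 simulated rows and 50 rows changed at each of several sizes. It recovered 10% of the rows changed by 0.5 on the log2 scale, 74% at 1, 98% at 2 and 100% at 4, and 8 of 149 calls were rows without a change. Far fewer rows passed than the 8782 of the real comparison. The adjustment was therefore stricter, and these shares do not give the power of the real comparison. For a list of 16 simulated genes shifted together by -0.45, camera called 100 of 100 draws at either correlation setting. It called 2 of 100 unchanged lists at the preset setting. These draws do not give the power of camera on the real lists. In the real data many more rows changed, genes of a list can vary together and p-values were adjusted over 49 lists. With an estimated correlation camera called 0 of the real lists in each comparison.

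The alternatives were quantile normalization applied again, a shift of every array to a common median, cyclic loess, filters on rows with a low mean at the 25th and 50th percentile, rows with 1 symbol only, an intensity trend with robust variances, the replicate letter as a block, leaving out each array, only the 4 arrays of the stages compared, a size threshold of 1 on the log2 scale, a linear trend on embryonic day, and the mean of all rows of a gene. A shift by the median deviation from row means, and the addition of ribosomal protein rows shared with pseudogenes, were chosen after the data were seen. There were 0 columns of values that could not be tied to a sample.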

Results

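Total RNA from the cortex of wild-type CD-1 mouse embryos, an outbred stock, was profiled on 8 arrays, with 2 samples (A and B) at each of embryonic days 11, 13, 15 and 18 (E11, E13, E15 and E18). Over these days progenitors lining the cortical ventricles divide and give rise first to deep-layer and then to upper-layer neurons. The table held 23332 rows, each a transcript cluster summarised over its core exons, of which 14996 carried exactly 1 gene symbol. Array medians lay between 7.61 and 7.83 on the log2 scale. The A and B arrays of a stage correlated across rows with Pearson's r of 0.985 to 0.989, whereas arrays of E11 and E18 correlated with r of 0.926 to 0.932, although rows are not independent replicates. The first principal component held 58.2% of the variance and placed the stages in the order E11, E13, E15 and E18. The labels did not say whether the samples of a stage came from separate embryos or litters, so p-values measured only the spread between these samples, which may be technical, and the number of arrays limited the precision. Each stage was collected from its own dams, so stage and collection could not be told apart. Sex was not part of the fit. Outside the naming rule, the Y-linked gene Eif2s3y was higher at E18 than at E11 (0.91 on the log2 scale, SE 0.21, limma adjusted p = 0.0155). Kdm5d, also Y-linked, was not called (0.35, SE 0.25), and a difference in sex between the samples was not excluded.

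Between E11 and E18 the cortex lost transcripts of dividing progenitors, embryonic blood and the dorsal midline, and gained those of neurons. Neurod6, a transcription factor of cortical excitatory neurons (transcript cluster 6953866), was at 4.83 ± 0.00 (SD, n = 2) at E11 and at 12.32 ± 0.08 at E18. This difference of 7.49 ± 0.08 on the log2 scale (SE, as in all differences that follow) was the largest rise among genes with a row of their own (limma adjusted p = 1.63e-06). The next largest rises were those of Dync1i1, a dynein intermediate chain, at 5.39 ± 0.13, and Sla, an adaptor of receptor signalling, at 5.25 ± 0.13. Other large rises included those of the glutamate receptor genes Grin2b (5.17 ± 0.19), Grm3 (5.14 ± 0.11) and Gria2 (4.72 ± 0.10), the adhesion gene Chl1 (5.16), the glycine receptor gene Glra2 (5.10), the exchange factor gene Tiam2 (4.93 ± 0.14) and the neuropeptide gene Nts (4.71 ± 0.10).

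The embryonic globin genes Hbb-y and Hba-x fell most, with differences of -6.96 ± 0.28 and -4.90 ± 0.23 on the log2 scale (limma adjusted p = 2.59e-05 and 3.59e-05). Saturation of the Hbb-y signal at E11 was not excluded, and if it was saturated its difference is a lower bound on the size of its fall. Otx2, a homeobox gene of the dorsal midline and choroid plexus, fell by 4.53 ± 0.35, and Wnt8b, a Wnt ligand of the cortical hem, fell by 3.23 ± 0.23. The retinoic acid binding protein genes Crabp2 (-4.42 ± 0.22) and Crabp1 (-3.97 ± 0.34) fell, and the growth factor gene Fgf15 fell by 3.42 ± 0.23. The DNA replication and repair genes Asf1b (-3.23 ± 0.12) and Exo1 (-3.20 ± 0.10) fell too. In all of these genes both E18 arrays lay on the same side of both E11 arrays, as the rule for naming them required. Among all 23332 rows 8782 differed between E18 and E11 at an adjusted p under 0.05, 4058 higher and 4724 lower at E18, a majority that turned under cyclic loess (4765 higher and 4420 lower). A difference of at least 1 on the log2 scale was reached by 1472 higher and 1374 lower rows. Across the 4 stages, limma's moderated F-test called 10424 rows, 44.7% of the table.

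All 37 measured genes of the mitosis list and all 32 of the DNA replication list fell from E11 to E18, over all rows and adjusted over the list alone. The list medians were -2.48 and -1.90. The kinetochore genes Cenpe (-3.17 ± 0.11) and Bub1 (-3.17 ± 0.14) fell, the chromatin regulator Uhrf1 fell by 2.85 ± 0.14, and the helicase subunit gene Mcm3 fell by 2.83 ± 0.12. Against all other genes, camera gave adjusted p = 3.19e-20 for mitosis and 1.03e-16 for DNA replication, and adjusted p = 0.340 for both with an estimated correlation. Among the replication-dependent histone genes, whose transcripts accumulate in S phase, 6 of 12 fell (7 adjusted over the list alone), with a median of -0.84. The camera adjusted p was 0.0044 for the histones, and adjusted p = 0.387 with an estimated correlation. H4c14 fell by 2.20 ± 0.48, with an SD of 1.15 between its E18 samples. The red blood cell list and the mixed list of choroid plexus and cortical hem fell over the same interval (medians -1.81 and -1.13).

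Of 13 early neuroepithelial and progenitor regulators, 9 fell and 1 rose, with the same counts adjusted over the list alone (median -1.29). Igf2bp1, an RNA-binding protein of the fetal brain, fell by 3.01 ± 0.07 and the architectural chromatin gene Hmga2 fell by 2.92 ± 0.09, while Myc rose by 0.94 ± 0.15. Among 21 radial glia genes 14 fell and 4 rose, again with the same counts adjusted over the list alone (median -1.29). Gli3, a mediator of hedgehog signalling, fell by 2.92 ± 0.07 and the apical membrane gene Prom1 fell by 2.07 ± 0.10. The members that rose included Tnc (3.76 ± 0.10), an extracellular matrix gene, and Slc1a3 (1.69 ± 0.07), a glutamate transporter that astrocytes also express. Against all other genes the camera adjusted p was 0.0016 for the progenitor regulators and 0.0023 for radial glia, and adjusted p = 0.342 and 0.519 with an estimated correlation. Intermediate progenitor genes went both ways, with 3 of 11 higher and 4 lower at E18, also adjusted over the list alone (median -0.08, mean -0.38, camera adjusted p = 0.549), from -2.17 ± 0.14 for Neurog1 to 1.03 ± 0.07 for Elavl2.

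Subunits of the BAF chromatin remodelling complex moved in opposite directions. All 5 genes of the progenitor list fell, also adjusted over the list alone, namely Actl6a (-1.49 ± 0.11), Ss18 (-1.24 ± 0.07), Dpf2 (-0.75 ± 0.07), Smarcc1 (-0.65 ± 0.06) and Phf10 (-0.43 ± 0.08). In the neuronal list Actl6b (3.43 ± 0.10), Smarca2 (2.38 ± 0.10) and Ss18l1 (1.84 ± 0.09) rose. Dpf3 differed by 0.35 ± 0.12, past the threshold when adjusted over the list alone (4 of 4) and not over all rows (adjusted p = 0.058). A place in either list does not mean that a subunit is confined to those cells, and not every gene has a partner in the other list. By camera these lists had adjusted p = 0.0021 and 0.0022, and adjusted p = 0.340 for each with an estimated correlation.

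Genes of neuronal differentiation rose together from E11 to E18. All 25 measured genes of synaptic vesicles and release rose (25 adjusted over the list alone, median 1.83), among them the vesicle calcium sensors Syt4 (4.17 ± 0.14) and Syt1 (3.47 ± 0.12). So did 20 of 22 genes of glutamate receptors and the postsynaptic density (20 adjusted over the list alone, median 1.61) and 19 of 21 voltage-gated channel genes (20 adjusted over the list alone, median 1.98), among them the calcium channel gene Cacna1e at 3.45 ± 0.12. Of 16 genes of the maturing neuronal cytoskeleton, 14 rose (14 adjusted over the list alone, median 1.73), including the microtubule-binding gene Mapt (4.32 ± 0.10) and the kinase gene Camk2b (4.02 ± 0.11). In the GABA receptor and chloride transporter list, 10 of 11 genes rose, including Gabra2 (3.58 ± 0.15) and Gabra5 (3.56 ± 0.13). The chloride importer Slc12a2 fell by 0.45 ± 0.09, and the counts were the same adjusted over the list alone (mean 1.53). Newborn and migrating neuron genes had a median of 2.32, with 16 of 20 higher and 2 lower (3 lower adjusted over the list alone). The adhesion gene Cntn2 rose by 3.67 ± 0.12 and the transcription factor gene Nhlh1 fell by 1.52 ± 0.15. Camera adjusted p ranged from 1.19e-13 for synaptic vesicles to 3.39e-05 for GABA receptors over these 6 lists, with adjusted p from 0.294 to 0.340 with an estimated correlation. The axon guidance list was mixed, with 17 of 31 genes higher and 9 lower (19 and 10 adjusted over the list alone, median 0.52), Epha5 rising by 3.62 ± 0.11 and the midline repellent Slit2 falling (-2.06 ± 0.12). Its camera adjusted p was 0.0113, and adjusted p = 0.519 with an estimated correlation.

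Markers of cortical layers rose as well. Of 12 deep-layer genes 10 rose and 0 fell (10 and 1 adjusted over the list alone, median 1.10), with Pcp4 at 2.45 ± 0.14 and Ldb2 at 2.43 ± 0.11. Of 13 upper-layer genes 11 rose and 1 fell, also adjusted over the list alone (median 1.75). The transcription factor gene Mef2c rose by 4.19 ± 0.08 and the netrin receptor gene Unc5d by 3.15 ± 0.12, while Plxnd1 fell by 0.68 ± 0.10. The camera adjusted p was 1.58e-04 for deep and 3.17e-05 for upper layers, and adjusted p = 0.340 for each with an estimated correlation. GABAergic interneuron genes rose in 10 of 17 cases and fell in 2 (11 and 3 adjusted over the list alone, median 0.53), with the neuropeptide genes Npy at 3.05 ± 0.16 and Sst at 1.67 ± 0.25. The camera call of this list (adjusted p = 0.0165, and adjusted p = 0.567 with an estimated correlation) was absent when only the brighter rows above the 50th percentile were tested (adjusted p = 0.177).

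Subplate and Cajal-Retzius genes, markers of the earliest cortical neurons, went both ways. Of 10 subplate genes 4 rose and 3 fell (4 and 4 adjusted over the list alone), with a median of -0.01, a mean of 0.56 and a camera direction of up. The median was above 0 under the other 3 scalings, and camera did not call the list (adjusted p = 0.560). Of 9 Cajal-Retzius genes 2 rose and 6 fell, also adjusted over the list alone (median -0.44, camera adjusted p = 0.307), with Reln, the secreted guide of migrating neurons, at 2.54 ± 0.09 and the transcription factor gene Ebf2 at -1.69 ± 0.15. Among 14 genes of ventral telencephalic progenitors and striatum 4 rose and 5 fell, also adjusted over the list alone (median 0.00, mean -0.11, camera adjusted p = 0.906), with the dopamine receptor gene Drd1 at 2.69 ± 0.39 and the homeobox gene Isl1 at -2.70 ± 0.30. Of 12 thalamic and diencephalic genes 6 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.50), including Tcf7l2 (-2.43 ± 0.22) and Lhx9 (-2.33 ± 0.11). Camera called the thalamic list (adjusted p = 0.0074, and adjusted p = 0.519 with an estimated correlation), and the call was absent among rows above the 50th percentile of brightness (adjusted p = 0.070).

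In the lists of non-neuronal cells, astrocyte and gliogenesis genes rose in 15 of 25 cases and fell in 4 (16 and 4 adjusted over the list alone, median 0.77). Which cells carried these transcripts was not resolved in whole tissue. The transcription factor gene Nfix rose by 4.57 ± 0.07 and the glycolytic enzyme gene Aldoc by 3.79 ± 0.11, while Id3 (-2.07 ± 0.23) and Sox9 (-1.49 ± 0.09) fell. Microglia and macrophage genes rose in 9 of 19 cases and fell in 0, also adjusted over the list alone (median 0.47), including the cathepsin gene Ctss (1.03 ± 0.15) and the complement gene C1qc (1.02 ± 0.18). Camera called both lists, with adjusted p = 5.44e-04 for astrocytes and 0.0228 for microglia, and adjusted p = 0.340 and 0.577 with an estimated correlation. The microglia call was absent without the E18 A array (adjusted p = 0.066) and among rows above the 50th percentile of brightness (adjusted p = 0.182). In the oligodendrocyte lineage list 1 of 16 genes rose and 1 fell (1 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.608), with Olig1 at 1.18 ± 0.07 and Pdgfra at -0.80 ± 0.24.

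Vascular genes diverged within their lists. Of 20 endothelial genes 4 rose and 4 fell (4 and 6 adjusted over the list alone, median -0.02, which was above 0 under the other 3 scalings, mean 0.15, camera direction up with adjusted p = 0.896). The thyroid hormone transporter Slco1c1 rose by 4.06 ± 0.17 and the tight junction gene Cldn5 by 1.38 ± 0.13, while the glucose transporter Slc2a1 fell by 1.26 ± 0.09. Of 14 pericyte and smooth muscle genes 4 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.510), with Rgs5 at 2.32 ± 0.10 and Notch3 at -1.97 ± 0.10. Of 21 genes of meninges and mesenchyme 4 rose and 8 fell, also adjusted over the list alone (median -0.56, camera adjusted p = 0.510), including Aldh1a2 (2.58 ± 0.24) and Lum (-2.75 ± 0.63).

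All 11 measured red blood cell genes fell, also adjusted over the list alone (median -1.81), as did 13 of 20 genes of the choroid plexus and cortical hem (13 adjusted over the list alone, median -1.13). Camera gave adjusted p = 2.61e-06 and 4.36e-04 for these lists, and adjusted p = 0.340 and 0.519 with an estimated correlation. Of 15 genes of surface ectoderm and muscle 2 fell and 0 rose, also adjusted over the list alone (median -0.02, above 0 under the other 3 scalings, camera adjusted p = 0.731), with the epithelial gene Epcam at -2.59 ± 0.15. The caudal Hox genes, which mark hindbrain and spinal cord, gave 0 calls among 14 genes by limma, also adjusted over the list alone (median -0.02, above 0 under the other 3 scalings, mean 0.01, camera direction up with adjusted p = 0.896), and fry gave adjusted p = 0.796 for the list. The largest differences of the Hox list were 0.22 ± 0.08 for Hoxd3 and -0.18 ± 0.17 for Hoxc8.

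**Figure D1:**
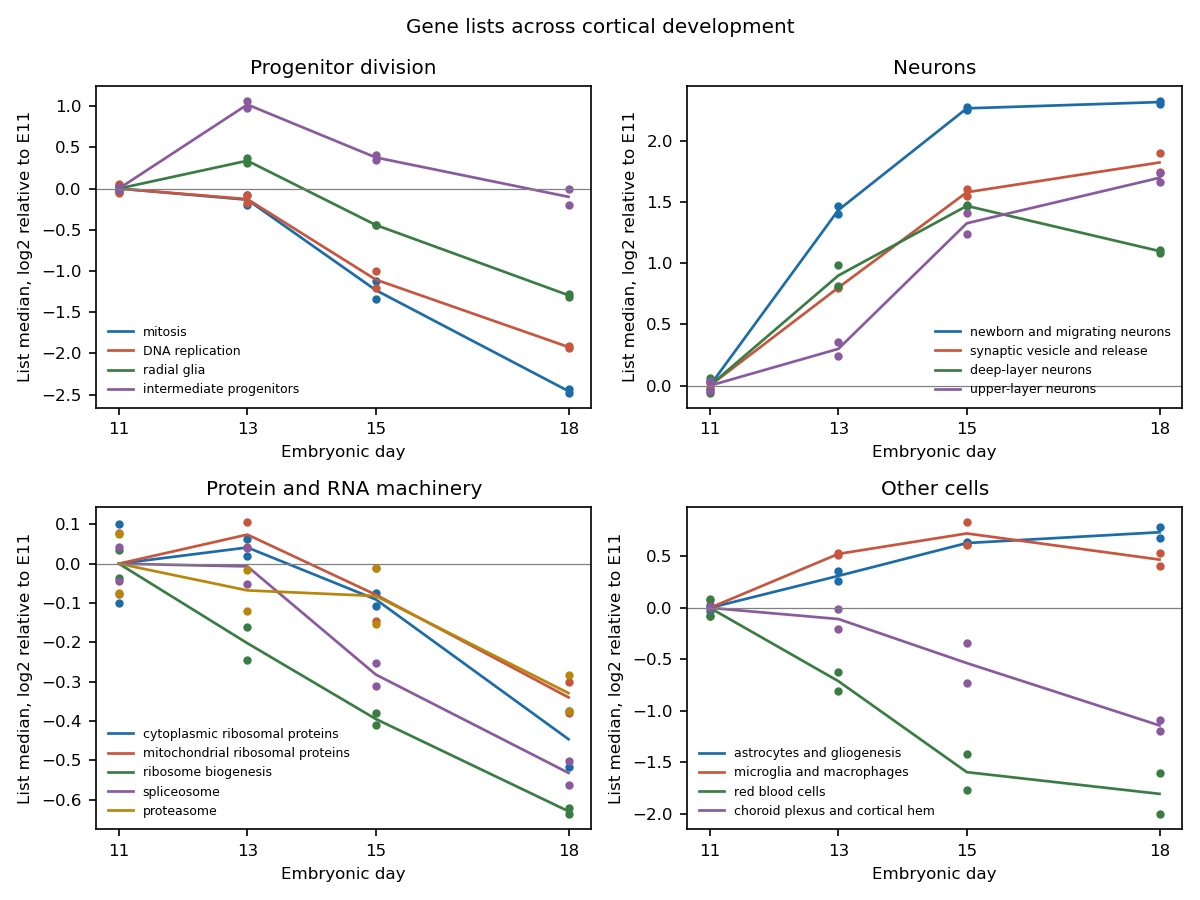
Median of gene lists in each array, in log2 units relative to the mean of the E11 arrays (y axis), against embryonic day (x axis). Points are single arrays, lines join the stage means of 2 arrays, and the panels group progenitor, neuronal, machinery and other cell type lists. At E18 the mitosis list lay at -2.46 ± 0.03 and the cytoplasmic ribosomal protein list at -0.45 ± 0.10 (SD, n = 2). These SDs leave out the spread of the E11 arrays, and the machinery panel has a narrower y axis than the others.

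The series asked how messenger RNAs of ribosomal proteins are regulated through cortical development. Of 80 listed cytoplasmic ribosomal protein genes, 16 had a row of their own, 9 of the large and 7 of the small subunit. From E11 to E18, 8 of the 16 fell and 0 rose, and 9 fell when adjusted over the list alone. Rpl4 (transcript cluster mean 7.75 ± 0.41 at E11 and 6.44 ± 0.24 at E18, SD, n = 2) fell by 1.31 ± 0.23 on the log2 scale, Rps18 by 1.05 ± 0.28, Rpsa by 0.96 ± 0.18 and Rpl31 by 0.86 ± 0.24. Rpl23 (-0.56 ± 0.15), Rpl10a (-0.48 ± 0.14), Rps3 (-0.47 ± 0.12) and Rpl8 (-0.43 ± 0.12) also fell. The other 8 genes were not called over all rows and ranged from -0.48 ± 0.18 for Rplp0 to 0.30 ± 0.11 for Rpl37. Rps20, at -0.33 ± 0.11, passed when adjusted over the list alone (adjusted p = 0.0447) and not over all rows (adjusted p = 0.063). Rpl4, Rps18 (7.25 at E11) and Rpl31 (5.91) had dim rows, near or below the E11 array medians of 7.62 and 7.67. The bright rows of Rpl8 (12.57) and Rps3 (11.74) fell less, and that of Rps9 (12.06) was not called (-0.16 ± 0.08). Rpsa, with a large fall, was brighter (9.28), and the dim rows of Rps15 (6.60) and Rps24 (6.92) were not called.

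The list median was -0.45, which lay at the percentile 0.28 of 10000 random lists matched on mean expression. Genes of the random lists were drawn independently, so the percentile overstates how rare the median was if ribosomal protein genes vary together. Fry, which tests whether the genes move on balance in the same direction, gave adjusted p = 0.0247. Camera, which compares the list with all other genes, gave adjusted p = 0.054 and did not pass, and gave adjusted p = 0.575 with an estimated correlation. The 9 large-subunit genes (5 fell, 5 adjusted over the list alone, median -0.48) and the 7 small-subunit genes (3 fell, 4 adjusted over the list alone, median -0.33) each had camera adjusted p = 0.177. The list median was -0.40 with adjusted p = 0.041 under cyclic loess, -0.52 with adjusted p = 0.026 without the E11 A array, and -0.52 with adjusted p = 0.038 without the E18 A array. It shrank to -0.29 with adjusted p = 0.129 without the E11 B array, and camera gave adjusted p = 0.182 among rows above the 50th percentile of brightness. The count of 8 fallen genes dropped to 1 without the E11 B array, to 2 without the E18 B array, and to 5 without any of the E11 A, E13 A and E13 B arrays. Rpl31 lost its call under quantile normalization applied again and under cyclic loess (adjusted p = 0.0536), and without any single array of E11, E13 or E18 (adjusted p from 0.0548 without E18 A to 0.163 without E11 A). Rpl37 was called higher under cyclic loess (adjusted p = 0.0291) and with arrays at a common median (adjusted p = 0.0489).

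**Figure D2:**
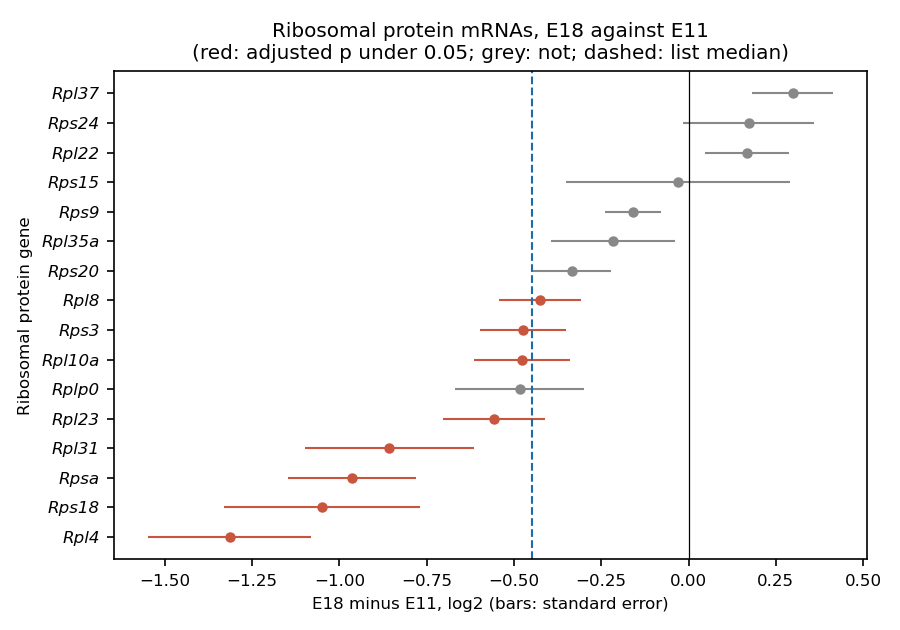
Difference between E18 and E11 on the log2 scale (x axis) for each of the 16 measured ribosomal protein genes (y axis), from 2 arrays per stage. Bars are standard errors of the limma fit over 8 arrays, red points had an adjusted p under 0.05, and the dashed line marks the list median of -0.45. Values run from -1.31 for Rpl4 to 0.30 for Rpl37.

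Members of the list did not all follow the same course. Measured against the list median on the same array, 4 of the 16 genes changed over the stages (limma F-test, adjusted over the list alone). Rpl37 ended 0.78 ± 0.11 above the course of the list from E11 to E18 (adjusted p = 0.0022), Rps24 ended 0.65 ± 0.13 above it (adjusted p = 0.0111) and Rpl22 ended 0.65 ± 0.16 above it (adjusted p = 0.0150). Rpl4 ended below it, at -0.83 ± 0.18 (adjusted p = 0.0113). The count of 4 became 1 without the E11 A array and 2 without any of the E13 A, E13 B and E15 A arrays. Of 5 measured paralogs of ribosomal protein genes 3 fell and 0 rose, also adjusted over the list alone, namely Rps27l (-1.58 ± 0.20), Rpl7l1 (-0.75 ± 0.08) and Rps4l (-0.72 ± 0.18). Rpl39l and Rpl3l differed by -0.21 ± 0.10 and -0.08 ± 0.09, and camera did not call the paralogs (adjusted p = 0.056), except without the E11 A array (adjusted p = 0.0491) or the E18 B array (adjusted p = 0.0277), and with all arrays they had adjusted p = 0.519 with an estimated correlation. Among 13 further rows that paired a ribosomal protein symbol with pseudogene symbols and so could not be assigned to either, 1 rose and 2 fell, with a median of -0.18. Genes with near-identical pseudogenes can share probes, so levels of ribosomal protein genes in general are uncertain on this kind of array.

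In no single step between stages did the ribosomal protein list pass the test against all other genes. The list median was 0.03 from E11 to E13, where it lay below 0 under the other 3 scalings and at -0.14 with arrays shifted to a common median, 0.05 from E13 to E15, where the mean was -0.09, and -0.28 from E15 to E18, where it was -0.14 to -0.18 under the other 3 scalings. None of the 16 genes passed over all rows or adjusted over the list alone in the first step. In the second step 2 fell over all rows, Rpl10a (-0.54 ± 0.14) and Rps20 (-0.46 ± 0.11), and 0 adjusted over the list alone. In the last step 0 passed either way, and camera gave adjusted p = 0.0965. This became 0.0317 with arrays shifted to a common median and 0.0344 under quantile normalization applied again. With an estimated correlation and the deposited values, camera called 0 lists in this step (lowest adjusted p = 0.309). For the earlier steps camera gave a downward direction with adjusted p = 0.542 and 0.704.

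Other components of gene expression fell over the same interval. Of 43 ribosome biogenesis genes 35 fell and 0 rose from E11 to E18 (36 adjusted over the list alone, median -0.62), including the small-subunit processome genes Mphosph10 (-1.42 ± 0.11) and Utp20 (-1.40 ± 0.09). Of 68 mitochondrial ribosomal protein genes 36 fell and 3 rose (39 and 3 adjusted over the list alone, median -0.35), with Mrpl13 at -1.16 ± 0.12, Mrpl40 at -1.03 ± 0.10 and Mrpl48 at 1.03 ± 0.15. Of 25 translation initiation factors 14 fell and 0 rose, also adjusted over the list alone (median -0.30), including Eif3a (-1.04 ± 0.08) and Eif5b (-0.95 ± 0.13). The camera adjusted p was 1.56e-10, 1.34e-04 and 0.0023 for these 3 lists, and adjusted p = 0.371, 0.577 and 0.519 with an estimated correlation. Of 6 elongation factor genes 2 rose and 1 fell, also adjusted over the list alone (median 0.18, camera adjusted p = 0.338). These were Eef1a2, the isoform of neurons and muscle (2.31 ± 0.12), the elongation factor kinase Eef2k (0.97 ± 0.09) and Eef1b2 (-0.36 ± 0.09).

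Genes of the mTOR pathway and of neural RNA-binding proteins went both ways. Of 19 genes of the mTOR pathway 6 rose and 6 fell, also adjusted over the list alone (median 0.08, mean -0.00, camera adjusted p = 0.750), with Sesn1 at 0.72 ± 0.10, Ddit4 at 0.54 ± 0.11, the translational repressor Eif4ebp2 at -0.86 ± 0.13 and Sesn3 at -0.80 ± 0.09. Of 32 neural RNA-binding protein genes 17 rose and 10 fell (18 and 10 adjusted over the list alone, median 0.49, camera adjusted p = 0.054). Camera called this list without the E11 A array (adjusted p = 0.0342), without either E13 array (0.0463) and without E18 B (0.0452), and with all arrays it had adjusted p = 0.519 with an estimated correlation. The splicing regulators Rbfox1 (3.87 ± 0.15) and Khdrbs2 (2.72 ± 0.09) rose, and the fetal genes Igf2bp1 (-3.01 ± 0.07) and Igf2bp3 (-2.11 ± 0.11) fell.

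In the first step, from E11 to E13, genes of newborn neurons and intermediate progenitors rose, and so did some genes of other lists. Neurod6 rose by 6.92 ± 0.08 of its 7.49. Nfix (3.81 ± 0.07) and Aldoc (4.50 ± 0.11), both of the astrocyte and gliogenesis list, rose as well, as did Ndrg2 (3.84 ± 0.08). All 20 newborn and migrating neuron genes rose, also adjusted over the list alone (median 1.44). Of 11 intermediate progenitor genes 9 rose and 0 fell, also adjusted over the list alone (median 1.02), among them Neurog1 (1.22 ± 0.14) and, chosen after their values were seen, the marker Eomes (1.48 ± 0.09) and the proneural gene Neurog2 (1.87 ± 0.13). Camera gave adjusted p = 6.10e-14 for newborn neurons and 1.88e-05 for intermediate progenitors, and adjusted p = 0.482 and 0.508 with an estimated correlation. Synaptic genes rose in 19 of 25 cases (20 adjusted over the list alone, median 0.80, camera adjusted p = 3.21e-08, and adjusted p = 0.508 with an estimated correlation). In the mitosis list 2 of 37 genes fell (1 adjusted over the list alone, median -0.12), and 14 to 16 fell, with a median of -0.29, under each of the other 3 scalings. Camera gave adjusted p = 2.43e-04 for mitosis, and adjusted p = 0.834 with an estimated correlation.

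Of 11 red blood cell genes 7 fell and 0 rose in this step (8 and 0 adjusted over the list alone, median -0.66, camera adjusted p = 1.24e-07, and adjusted p = 0.482 with an estimated correlation). Hemgn, a nuclear protein of erythroid cells, fell by 2.58 ± 0.17, while Hbb-y was at -0.06 ± 0.28. Hbb-y lay near the highest value of every E11 and E13 array (13.78 to 13.97), so saturation of its signal was not excluded and the small difference does not show an unchanged level. The retinoid-binding gene Crabp1 fell by 2.41 ± 0.34 and the matrix gene Hapln1 by 2.18 ± 0.19. AY036118, a cDNA of unassigned function, fell by 2.98 ± 0.53 and then rose by 3.47 ± 0.53 from E13 to E15, with SDs of 0.35 to 1.05 between samples of a stage. Ttr, the thyroid hormone carrier abundant in choroid plexus, rose from 7.21 ± 0.15 (SD, n = 2) to 13.26 ± 0.21, a difference of 6.05 ± 0.46, in the samples in which the neuronal genes rose.

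In all, 4731 rows differed between E13 and E11, 3790 higher and 941 lower (80.1% higher). The direction of this split depended on the scaling, since the array medians of E13 lay 0.17 above those of E11. Quantile normalization applied again gave 2342 higher and 2149 lower (52.1% higher), a common median 2308 and 3193 (42.0%), cyclic loess 2644 and 1662 (61.4%), and, chosen after the data were seen, a shift by the median deviation from row means 3413 and 1670 (67.1%). The count was 1871 without the E11 A array, 3052 without E11 B, 2082 without E13 A and 1980 without E13 B.

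**Figure D3:**
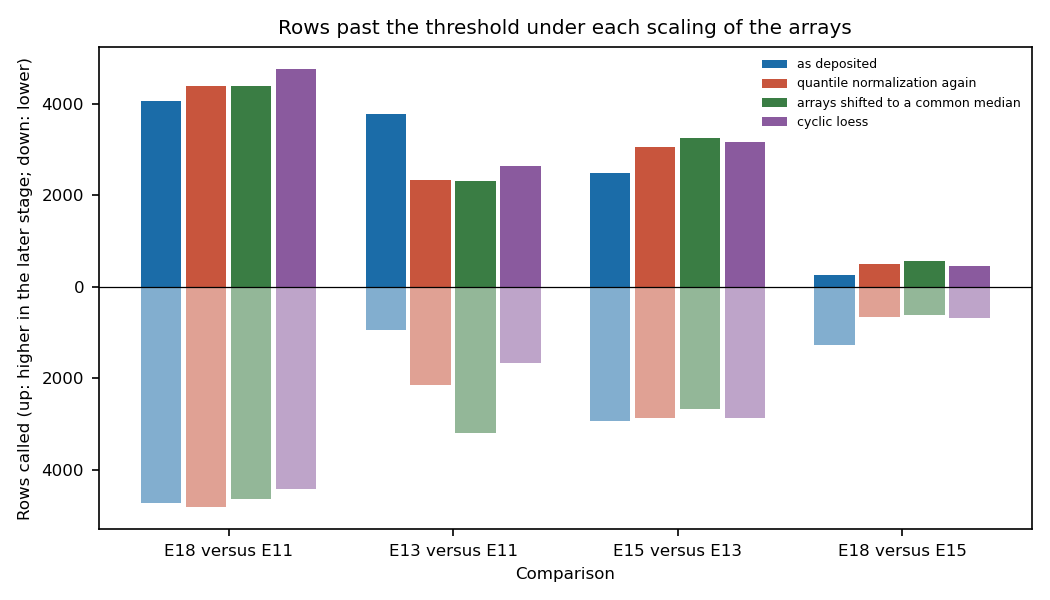
Number of rows with an adjusted p under 0.05 (y axis), higher in the later stage above 0 and lower below 0, for each comparison (x axis) and 4 scalings of the 8 arrays (colours). For E13 against E11 the split moved from 3790 higher and 941 lower in the values as deposited to 2308 higher and 3193 lower with arrays shifted to a common median.

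From E13 to E15 division genes fell and genes of mature neurons rose. All 37 mitosis and all 32 DNA replication genes fell, also adjusted over the list alone (medians -1.08 and -1.01, camera adjusted p = 1.11e-20 and 4.91e-18, and adjusted p = 0.461 for both with an estimated correlation). Radial glia genes fell in 15 of 21 cases and rose in 4 (15 and 5 adjusted over the list alone, median -0.72, camera adjusted p = 8.83e-04, and adjusted p = 0.553 with an estimated correlation). Of 13 upper-layer genes 10 rose and 1 fell, also adjusted over the list alone (median 0.92, camera adjusted p = 1.42e-04, and adjusted p = 0.461 with an estimated correlation), while of 12 deep-layer genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.25). Camera gave the deep-layer list adjusted p = 0.0022, and adjusted p = 0.461 with an estimated correlation. Synaptic genes rose in 20 of 25 cases (21 adjusted over the list alone, median 0.82, camera adjusted p = 2.39e-09, and adjusted p = 0.461 with an estimated correlation). Sla rose by 4.22 ± 0.13, Dync1i1 by 3.79 ± 0.13, the melanocortin receptor gene Mc4r by 3.51 ± 0.12 and the zinc finger gene Hivep2 by 3.14 ± 0.11.

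Hbb-y (-4.70 ± 0.28, a lower bound on the size of its fall if its E13 signal was saturated) and Hba-x (-3.91 ± 0.23) fell between E13 and E15. Gmnc, a regulator of multiciliated cell formation, fell by 2.72 ± 0.24, Crabp2 by 2.70 ± 0.22 and the progenitor transcription factor gene Dmrta1 by 2.45 ± 0.19. Choroid plexus and hem genes fell in 9 of 20 cases and rose in 0 (10 and 0 adjusted over the list alone, median -0.62, camera adjusted p = 8.61e-05, and adjusted p = 0.553 with an estimated correlation). Ttr lay at 11.94 in the A and 13.37 in the B sample of E15. Among all rows 5420 differed, 2492 higher and 2928 lower at E15, a majority that turned with arrays at a common median (3248 higher and 2667 lower). The count was 2480 without the E13 A array, 3093 without E13 B, 3377 without E15 A and 3602 without E15 B.

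From E15 to E18 the fall of division genes continued. Of 37 mitosis genes 36 fell and 0 rose, also adjusted over the list alone (median -1.20), and of 32 DNA replication genes 27 fell (32 adjusted over the list alone, median -0.79). Intermediate progenitor genes fell in 8 of 11 cases and rose in 0 (10 and 1 adjusted over the list alone, median -1.02), with Neurog1 at -1.24 ± 0.14 and Tfap2c at -1.22 ± 0.09. Against all other genes camera gave adjusted p = 1.20e-24, 1.59e-16 and 1.62e-05 for these lists, and adjusted p = 0.497 for each with an estimated correlation. Glutamate receptor and postsynaptic genes rose in 5 of 22 cases and fell in 0 (7 and 0 adjusted over the list alone, median 0.18, and 0.31 to 0.32 under the other 3 scalings, camera adjusted p = 4.52e-09, and adjusted p = 0.342 with an estimated correlation). The peptide gene Nts rose by 3.27 ± 0.10, the contactin genes Cntn6 and Cntn4 by 2.91 ± 0.12 and 1.87 ± 0.08, the receptor tyrosine kinase gene Met by 2.07 ± 0.15 and the secreted factor gene Tafa1 by 1.86 ± 0.28. Olig1, a transcription factor of the oligodendrocyte lineage, rose by 0.95 ± 0.07.

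Ttr fell by 5.23 ± 0.46 to 7.42 ± 0.40 (SD, n = 2), and Hbb-y (-2.20 ± 0.28), Isl1 (-2.10 ± 0.30) and Nhlh1 (-1.88 ± 0.15) fell in this last step. Of 1532 rows that differed, 268 were higher and 1264 lower at E18 (17.5% higher), and this split too moved with the scaling, as the array medians differed by -0.14. It was 490 higher and 651 lower (42.9%) under quantile normalization applied again, 569 and 617 (48.0%) with a common median, 454 and 678 (40.1%) under cyclic loess, and 430 and 985 (30.4%) after the shift by the median deviation. The comparison rested on both E18 arrays, since 4 rows passed without E18 A and 1 without E18 B, 220 without E15 B, 694 without E15 A, 699 without either E11 array and 688 without either E13 array. With only the 4 arrays of these stages in the fit, limma called 0 rows, and 5180 had an unadjusted p under 0.05.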

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

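The shift of arrays by the median deviation from row means and the addition of rows shared with pseudogenes to the ribosomal protein list were chosen after the results had been seen. No gene list, and none of the genes refitted for E18 against E11, was called in the opposite direction in that comparison under any alternative that was run. The majority direction of the called rows did turn, for E13 against E11 with a common median (2308 higher and 3193 lower), for E15 against E13 with a common median (3248 higher and 2667 lower) and for E18 against E11 under cyclic loess (4765 higher and 4420 lower). The 24 genes with the largest differences from E11 to E18 passed in all of 406 refits (highest adjusted p = 0.00648), whereas the 21 ribosomal protein genes and paralogs changed their call in 51 of 347. Leaving out each array gave counts between 6671 and 8732 for E18 against E11 (8782 with all arrays), between 1871 and 4273 for E13 against E11, between 2480 and 4718 for E15 against E13, and between 1 and 699 for E18 against E15, where a stage left with 1 array was assumed to vary like the others. It gave between 1 and 7 ribosomal protein genes lower at E18, between 1 and 4 apart from their list, and a list median between -0.52 and -0.29. Requiring a difference of at least 1 on the log2 scale left 2846 rows for E18 against E11, 806 for E13 against E11, 951 for E15 against E13 and 279 for E18 against E15. With only the 4 arrays compared the counts were 2606, 2962 and 0 for the 3 steps, from fewer residual degrees of freedom. For genes changed across the 4 stages, a linear trend on embryonic day called 6300 rows in place of 10424, and the cause was not tested. For E18 against E15 the count of 1532 became 2659 and 3501 above the 25th and 50th percentile of brightness, 2534 among rows with 1 symbol and 2853 with an intensity trend and robust variances. The first 3 of these tested fewer rows, and the cause of the last was not tested. The camera test of the 16 ribosomal protein genes crossed the threshold under quantile normalization applied again (median -0.43, adjusted p = 0.040), cyclic loess (-0.40, adjusted p = 0.041), the shift by median deviation (-0.40, adjusted p = 0.047) and the added shared rows (-0.29, adjusted p = 0.036). Its adjusted p over all alternatives ran from 0.0265 to 0.575, and the cause was not tested. With an estimated correlation 0 of the 28 gene lists called for E18 against E11 passed. Of other alternatives for single lists, 821 gave the same call, 9 crossed to the called side and 32 lost it, 28 of the latter with the estimated correlation. Signal over background was not measured, so dim rows are limited by an unknown floor.

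The labels did not say whether the letters A and B link samples across stages. Deviations from the stage means of samples with the same letter correlated across rows with r of -0.036 to 0.087 over the 6 pairs of stages. Correlations this weak show no strong link, but with 2 arrays per stage they do not exclude one. With the letter as a replicate block the count for E18 against E15 was 795 and the ribosomal protein median of -0.45 had camera adjusted p = 0.038, while the counts for the other comparisons stayed within 1.5 times of those without the block, at 8506 for E18 against E11.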

Other observations

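All tests of explanations given here were chosen only after the result was seen, except the comparison of ribosomal protein genes with lists matched on brightness. Several lists not described above also changed from E11 to E18. Of 23 spliceosome genes 18 fell and 0 rose (20 and 0 adjusted over the list alone, median -0.51), including Lsm2 (-1.23 ± 0.15) and Lsm3 (-1.14 ± 0.11). Of 26 proteasome genes 14 fell and 0 rose, also adjusted over the list alone (median -0.29), with the ATPase subunit gene Psmc5 at -0.77 ± 0.07. Camera gave adjusted p = 2.61e-06 and 5.44e-04 for these lists, and adjusted p = 0.396 and 0.575 with an estimated correlation. Of 12 imprinted growth genes 8 fell and 1 rose, also adjusted over the list alone (median -0.97, camera adjusted p = 0.0049, and adjusted p = 0.567 with an estimated correlation). The paternally expressed Dlk1 fell by 2.48 ± 0.18 and the growth regulator Grb10 by 2.42 ± 0.14, while Ndn, a gene of postmitotic neurons, rose by 0.95 ± 0.12.

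Genes of glucose metabolism exchanged members. Of 15 glycolysis genes 6 rose and 8 fell, also adjusted over the list alone, with a median of -0.50, a mean of 0.07 and camera adjusted p = 0.896 in the lower direction. Hexokinase Hk2 fell by 2.74 ± 0.11 and the lactate exporter Slc16a3 fell too (-2.57 ± 0.16), while aldolase Aldoc rose by 3.79 ± 0.11 and phosphofructokinase Pfkp by 2.70 ± 0.09. Of 57 oxidative phosphorylation genes 5 rose and 5 fell (0 and 0 adjusted over the list alone, median -0.04, which was above 0 under cyclic loess, camera adjusted p = 0.731). Of 19 immediate early genes 3 rose and 3 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.896), with Nr4a3 at 3.05 ± 0.13 and Ier2 at -1.28 ± 0.16. Of 14 heat shock and unfolded protein response genes 1 rose and 3 fell, also adjusted over the list alone (median -0.11, camera adjusted p = 0.460), with Xbp1 at 0.43 ± 0.10 and the chaperone gene Hsp90b1 at -0.84 ± 0.09.

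Of 16 ribosomal protein genes 8 fell from E11 to E18, 8 were not called and 3 of these lay above 0, while the list did not pass camera (adjusted p = 0.054, and adjusted p = 0.575 with an estimated correlation) and the count dropped to 1 without the E11 B array and to 2 without E18 B. The array medians of E18 and E11 differed by -0.02, far less than the list median. The other 3 scalings, under which the list median was no higher than -0.40, could thus change it little and were a weak test of scale. Brightness as the source of the negative list median is argued against by its percentile of 0.28 among matched random lists. This holds only as far as genes drawn independently stand in for genes of a list that may vary together. The list median lay at the percentile 25.4 of random draws of as many genes from 185 genes of mitochondrial ribosomes, initiation, ribosome biogenesis, the spliceosome and the proteasome, but these lists were pooled after all of them had been seen to fall, so the test decided nothing. At E18 the ribosomal protein list lay at -0.45 ± 0.10 relative to E11 (SD, n = 2). This SD and those that follow cover the E18 arrays alone, and the E11 arrays of the ribosomal protein list had an SD of 0.14. Ribosome biogenesis lay at -0.63 ± 0.01, the spliceosome at -0.53 ± 0.04, mitochondrial ribosomal proteins at -0.34 ± 0.06 and the proteasome at -0.33 ± 0.06. Elongation factors (0.18 ± 0.01), the mTOR pathway (0.09 ± 0.03) and oxidative phosphorylation (-0.05 ± 0.10) showed no such fall. Falls were thus not confined to ribosomal proteins among the lists measured. Since the falling lists were picked after they had been seen to fall, they decide nothing about a shared cause. A change in the share of dividing cells and the separate collection of each stage stay open and were not tested.

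Ttr was high at E13 and E15 and near its E11 level at E18, with 13.41 and 13.11 in the E13 samples, 11.94 and 13.37 in the E15 samples and a mean of 7.42 ± 0.40 at E18 (SD, n = 2). From E11 to E13 the list medians of attached tissues decided nothing, at -0.66 for red blood cells (7 of 11 lower, 0 higher, while a row shared by both adult beta-globin genes rose by 1.53), 0.27 for endothelial cells (5 of 20 higher, 0 lower), -0.16 for meninges (3 of 21 higher, 1 lower) and -0.072 for choroid plexus and hem (3 of 20 higher, 3 lower). The last list mixed hem genes with choroid plexus genes, of which Kcne2 rose by 1.14 ± 0.16 (limma adjusted p = 0.0072), and Clic6 (1.43 ± 0.41), Folr1 (0.49 ± 0.29), Aqp1 (0.43 ± 0.28) and Kl (0.08 ± 0.10) were not called. Between the E15 samples, B exceeded A by 1.43 for Ttr, by a median of 0.32 over the choroid plexus and hem list, 0.86 over Kcne2, Clic6, Folr1 and Aqp1, which were chosen after Ttr was seen, 0.83 over meninges and 0.11 over endothelial cells. The amount of choroid plexus, meninges, vessels or blood in the dissected tissue and the growth of the choroid plexus between stages stay open.

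Hbb-y (-4.70 ± 0.28, a lower bound if its signal at E13 was saturated) and Hba-x (-3.91 ± 0.23) fell from E13 to E15. Less blood alone in the later samples is argued against by a row carrying the symbols of both adult beta-globin genes, assignable to neither, which differed by 0.42 ± 0.35 in the same step (limma adjusted p = 0.438) after 1.53 from E11 to E13 (adjusted p = 0.030). The adult row read 8.76 and 8.02 in the E13 samples and 9.05 and 8.57 in the E15 samples. The median of the 9 other red blood cell genes was -0.21 in this step. Of these, Slc4a1 (-1.01 ± 0.14), Rhag (-0.46 ± 0.11) and Epb42 (-0.41 ± 0.09) fell past the threshold. Only Alas2 (0.05 ± 0.12, not called) lay above 0. A smaller loss of blood, and a change in the globin genes that circulating cells express, stay open and were not tested.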
